A study of Mus musculus with 18 samples.

How the data were processed

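The deposited values were MAS5 signal intensities on a linear scale, per the submitters' processing notes, which gave no software version. There were 45101 probe sets for 18 arrays. The 2% trimmed mean per array ran from 47.5 to 148, a 3.11-fold range, so each array was scaled to a common trimmed mean of 82.4. Signals were then used as log2(signal + 4.12), the offset being 5% of that mean.

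The probe annotation listed 35890 of the probe sets, 34958 with 1 gene and 932 with several, and 9211 had no listed gene. Of those with 1 gene, 34754 were matched by Entrez ID to the GRCm38.p6 gene table, which was used for names only. Genome positions were not used here. Each of 18194 genes was read by the probe set with the highest mean, and the upper 60% by mean log2 signal, 10916 genes, were tested; the dimmest gene kept had a mean of 4.74. Some genes are not analysed here.

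A linear model of 6 group means over all 18 arrays (12 residual degrees of freedom) was fitted with limma, with a trended and robust variance prior, for 9 comparisons. P-values were two-sided and adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05. With 3 arrays against 3, the smallest exact two-sided permutation p is 0.1, so single genes rest on the variance shared by the model. The comparisons, the gene lists, the alternatives named as planned and the rule for naming genes were chosen before the data were examined.

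There were 21 gene lists with 394 entries and 368 different genes, of which 348 were on the array and 307 were tested. They covered p53 targets in general, in cell death and in DNA repair, mitosis, the G1/S transition and replication, immediate early genes, telomere maintenance, replication stress, interferon and estrogen responses, cholesterol synthesis, the endoplasmic reticulum and integrated stress, heat shock, secreted senescence factors, ribosome biogenesis and markers of mesenchymal, epithelial, blood, endothelial, muscle and neural cells. Each was tested with camera, with a preset correlation of 0.01 and with a correlation estimated from the data, and with fry, adjusted over the 21 lists within a comparison.

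Genes were named by this rule: Esr1 and Zfp365 everywhere; among genes past the threshold whose groups did not overlap, the 10 largest changes each way in the main comparison and in the difference of the 4-OHT effect, and 5 in the others; and for each list up to 4 genes past the threshold, or up to 2 with the largest change where none passed. A gene named once could be given in other comparisons. Further genes are said to have been chosen after their values were seen.

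Deviations from the group means correlated between arrays of the same replicate number, above 0.1 in every pair, in p53ER cells with 4-OHT against vehicle (r 0.21 to 0.45) and against 0 h (0.27 to 0.47), in uninfected cells with 4-OHT against vehicle (0.31 to 0.62) and in the difference of the 4-OHT effect. In the other 5 comparisons at least 1 pair fell short, the lowest r being -0.21. Over all groups, 14 of the 18 arrays correlated best with an array of their own number. The labels do not say what a number stands for, so the block was used as an alternative.

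The median correlation of an array with the other 17 ran from 0.899 to 0.961. The actin 3'/5' ratio of the control probe sets ran from 1.00 to 1.22 and the Gapdh ratio from 0.782 to 0.950.

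The pipeline was tested on simulated data for the main comparison only, in 20 data sets with 50 changed genes per size. It recovered 5.60% of genes at a log2 change of 0.5, 43.9% at 1, 85.5% at 2 and 96.1% at 3, with 4.65% of calls false and 1 call of the wrong sign. A list of 40 genes shifted by 0.5 was found in 20 of 20 sets and an unshifted one in 0. The simulation held no differences between replicate numbers or between whole arrays.

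The alternatives tried were quantile normalization, no offset, a larger offset of 20% (16.5), no filter and a stricter filter (upper 40%) on dim genes, all probe sets, the replicate number as a block (10 residual degrees of freedom), only the groups compared, a variance prior without trend and robustness, array weights, a minimum fold of 1.5 and leaving out each array in turn. Leaving out the 3 arrays farthest on the first principal component, with and without the block, and leaving out replicate 3 of every group were chosen after the data were seen. Without those 3 arrays the groups no longer held the same replicate numbers. R 4.3.3, limma 3.58.1, data.table (version 1.17.8), statmod 1.5.0 and matplotlib 3.10.9 were used.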

Results

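Expression was measured on 18 Affymetrix arrays of RNA from a mouse cell line called TKO, described in the labels as having dysfunctional telomeres. Some of the cells carried p53ER, a fusion of the tumour suppressor p53 to an estrogen receptor that is inactive until 4-hydroxytamoxifen (4-OHT) is added, and the others were uninfected. Each cell type was sampled at 0 h, after 4 h with 100 nM 4-OHT and after 4 h with vehicle, with 3 arrays in each of the 6 groups. The study chose the 4 h time point to list potential direct targets of p53, and its title concerns the zinc finger gene ZNF365 (Zfp365 in the mouse), fragile sites and telomeres. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical. The 2% trimmed mean signal ran from 47.5 to 148 between arrays before scaling, and the number of arrays limits the precision of every value.

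The arrays also differed in ways the groups did not explain. On the first principal component, which held 23.9% of the variance, 3 arrays of different groups lay apart: uninfected 0 h replicate 2, p53ER vehicle replicate 1 and, less far, p53ER 0 h replicate 3. The second component, with 21.8%, separated replicate 3 of every group from replicates 1 and 2. By the median correlation with the other 17 arrays, 6 arrays lay below the median minus 3 median absolute deviations (0.937): those 3 and replicate 3 of p53ER with 4-OHT, p53ER with vehicle and uninfected 0 h.

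The main question was which genes p53 switches on within 4 h, read from p53ER cells with 4-OHT against the same cells with vehicle. Mdm2, which encodes the ubiquitin ligase that limits p53, was 7.57-fold higher with 4-OHT (log2 change +2.92, SE 0.41). Its mean log2 signal was 10.5 ± 0.65 with 4-OHT and 7.60 ± 1.02 with vehicle (SD, n = 3). Pmaip1, which encodes the pro-apoptotic protein Noxa, was higher by a log2 change of +3.38 (SE 0.52), at 7.83 ± 0.81 against 4.44 ± 0.85 (SD, n = 3). Its signal with vehicle was near background, so the size depends on the offset (+2.78 with a larger offset, +3.72 with none). For both genes all 3 arrays with 4-OHT lay above all 3 with vehicle. These 2 genes were the ones past the threshold among 10916 tested, both higher (limma, adjusted p = 0.0344 and 0.0361). A second Mdm2 probe set rose by 2.95 (SE 0.28, limma adjusted p = 7.1e-05 over all probe sets), while the third was near the floor and differed by -0.02 (SE 0.52). At an unadjusted p under 0.05, 354 genes passed, against 545.8 by chance. The number by chance is the same in all 9 comparisons. With the replicate number as a block, 8 genes passed, all higher: Mdm2, Pmaip1, Phlda3, Cdkn1a, Nlrc5, Btbd11, Ddit4l and Zfp365. Of these, Phlda3, Cdkn1a, Nlrc5, Btbd11 and Ddit4l were named after their values were seen.

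Both calls were sensitive to leaving out 1 array, which also lowers the number of arrays. Mdm2 was no longer past the threshold without 4-OHT replicate 1, 2 or 3 (limma adjusted p = 0.0604, 0.0776 and 0.284) or without vehicle replicate 1 or 2 (0.0659 and 0.123), and Pmaip1 likewise (0.0604, 0.114, 0.447, 0.124 and 0.123). Of all genes, none passed without any 1 of the 4-OHT arrays (355, 349 and 274 at an unadjusted p under 0.05), 1 without vehicle replicate 1 or 2, and 5 without vehicle replicate 3, while the log2 change of Mdm2 stayed between +2.50 and +3.49.

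Textbook p53 targets, a list fixed in advance, rose together in p53ER cells with 4-OHT. Of its 41 tested genes 35 had a positive change, with a median log2 change of +0.55. Adjusted over the list alone, 9 genes passed, all higher. Besides Mdm2 and Pmaip1 these were the cell cycle inhibitor Cdkn1a (+2.19, SE 0.49), the cyclin G gene Ccng1 (+2.11, SE 0.56), Trp53inp1 (+2.60, SE 0.68), Phlda3 (+1.43, SE 0.24), Pidd1 (+1.30, SE 0.42), Tnfaip8 (+0.84, SE 0.25) and Ei24 (+0.78, SE 0.26). The 7 beyond Mdm2 and Pmaip1 did not pass over all genes, where their adjusted p ran from 0.0704 for Phlda3 to 0.998 for Tnfaip8, Pidd1 and Ei24. A second Ccng1 probe set rose by 1.77 (SE 0.27, limma adjusted p = 0.0260 over all probe sets), and the remaining one differed by +1.91 (SE 0.41, adjusted p = 0.540). Without p53ER vehicle replicate 1 the change was +1.29 for Ccng1, +1.61 for Trp53inp1 and +0.58 for Btg2, and without 4-OHT replicate 3 it was +0.48 for Ei24. With the block, Phlda3 (limma adjusted p = 0.00859) and Cdkn1a (0.00859) passed over all genes, and 12 passed over the list alone, with Btg2 (+0.92), Dcxr (+1.00) and Ddit4 (+0.93) added. The list passed camera with a preset correlation (adjusted p = 3.7e-16) and with an estimated correlation (adjusted p = 0.0276), and fry (adjusted p = 0.0169). In 11 of its 41 genes all arrays with 4-OHT lay above all with vehicle and in 0 below, a share of 26.8% against 7.45% of all genes tested and 10% by chance.

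The p53 targets that promote cell death, which overlap with that list, also rose as a group. Their median was +0.42, with 15 of 16 positive and 4 past the threshold when adjusted over the list alone: Pmaip1, Trp53inp1, Pidd1 and Ei24. The group passed camera with the preset correlation (adjusted p = 1.4e-07) and with an estimated correlation (adjusted p = 0.0279). Without the 3 arrays that lay apart, both p53 lists kept a positive median (+0.41 and +0.39) but missed the threshold with an estimated correlation (adjusted p = 0.0757 for each). This left p53ER vehicle without replicate 1, so the groups no longer held the same replicate numbers. Without 4-OHT replicate 3, 4 of the p53 targets passed when adjusted over the list alone.

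**Figure D1:**
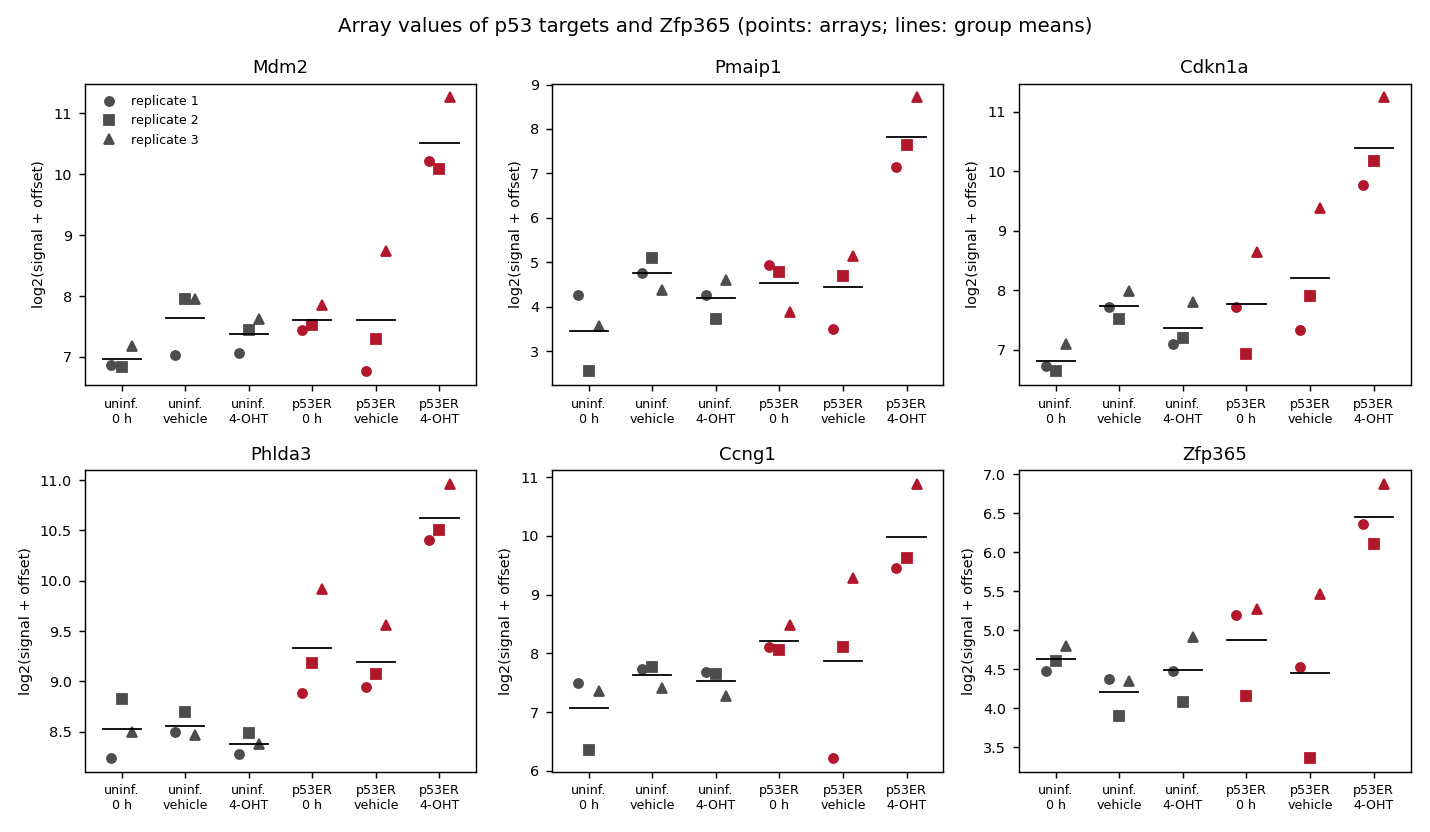
Log2 signal of 5 p53 targets and Zfp365 on each array, by group; points are arrays, their shapes the replicate numbers, and lines the group means of 3 arrays. The arrays of p53ER cells with 4-OHT lie above those with vehicle for Mdm2, Pmaip1, Cdkn1a, Phlda3, Ccng1 and Zfp365.

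Zfp365, the gene in the study's title, had a higher mean with 4-OHT than with vehicle in p53ER cells, where its signal with vehicle was near background. Its brighter probe set stood at 6.45 ± 0.39 with 4-OHT and 4.45 ± 1.05 with vehicle (SD, n = 3), a log2 change of +1.996 (SE 0.45; +1.49 with a larger offset and +2.31 with none), and the other probe set differed by +2.10 (SE 0.55). Every array with 4-OHT lay above every array with vehicle on the brighter probe set. The gene did not pass over all genes (limma adjusted p = 0.438), but passed with the block (adjusted p = 0.0381) and when adjusted over the list alone, among 25 replication stress genes (adjusted p = 0.01003). In uninfected cells the 4-OHT value was +0.28 (SE 0.45), and the difference between the cell types was +1.71 (SE 0.64, limma adjusted p = 1.00), so a difference between cell types was not shown for this gene. Against 0 h, Zfp365 in p53ER cells with 4-OHT differed by +1.57 (SE 0.45, limma adjusted p = 0.726). With vehicle against 0 h it differed by -0.43 in p53ER and -0.42 in uninfected cells, and between untreated cell types by +0.25 at 0 h and +0.25 with vehicle. On the other, dimmer probe set the 4-OHT value against 0 h was +2.49 (SE 0.55). There vehicle against 0 h gave +0.39 in p53ER and -0.44 in uninfected cells, and the cell types differed by -0.71 at 0 h and +0.11 with vehicle.

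Genes of the G1/S transition and DNA replication tended lower in p53ER cells with 4-OHT. Of the 27 tested, 4 were positive, with a median of -0.22; the largest values were Pola1 (+0.88, SE 0.93) and Cdc6 (-0.67, SE 0.27). The list passed camera with the preset correlation (adjusted p = 4.3e-05), a call lost with one estimated from the data (adjusted p = 0.525 with an estimated correlation). The mitotic genes had a median of -0.04 and a mean of +0.15, with Mki67 at +1.25 (SE 0.96) and Cenpe at +1.20 (SE 0.75). Among p53 targets in DNA repair the median was +0.27, with Polk at +0.92 (SE 0.35) and Ercc5 at +0.89 (SE 0.38). Telomere maintenance genes had a median of -0.07, with Tnks2 at +0.53 (SE 0.35) and Ten1 at -0.48 (SE 0.26). The replication stress list had a median of +0.12, and its largest value after Zfp365 was Smc1a (+0.71, SE 0.38). The medians without the 3 arrays that lay apart were +0.04 for DNA repair, -0.08 for replication stress, +0.14 for mitotic genes (23 of 29 positive) and -0.14 for replication genes, so only the last kept a clear direction. The p53ER vehicle group then lacked replicate 1, so these medians may also carry differences between replicate numbers.

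No other list passed camera in this comparison. Immediate early genes had a median of +0.07, with Junb at +0.77 and Atf3 at +0.53, and interferon response genes -0.04, with Ifit2 at +0.49 and Irf9 at -0.36. Estrogen response genes had a median of -0.02, with Nrip1 at +0.72 and Ccn5 at -0.37. The median was -0.12 for cholesterol synthesis (Idi1 +0.60, Mvk -0.36) and -0.08 for endoplasmic reticulum and integrated stress (Hsp90b1 +0.72, Sesn2 +0.71). Heat shock genes stood at -0.04 (Hsp90aa1 +0.69, Hspa1b -0.33), ribosome biogenesis genes at -0.13 (Rrp9 -0.95, Ncl +0.73) and secreted senescence factors at +0.02 (Mmp9 +0.77, Igfbp3 -0.63). The mean had the other sign than the median for the estrogen response (+0.03), the endoplasmic reticulum and integrated stress (+0.07) and the senescence factors (-0.01). When the 3 arrays that lay apart were left out the median was -0.25 for the senescence factors and -0.23 for ribosome biogenesis, and both passed with the preset correlation (adjusted p = 0.0327 and 0.0254) and not otherwise (adjusted p = 0.659 each with an estimated correlation). Markers of other cell types did not pass either. Their medians were +0.03 for mesenchymal (Postn +0.72, S100a4 +0.31), +0.18 for epithelial (Krt8 -0.76, Krt5 +0.75), +0.03 for blood (Cd74 +0.34, Csf1r -0.29) and +0.29 for endothelial markers (Kdr +0.53, Flt1 +0.04). Muscle markers stood at -0.00 (Ckm -0.15, Des +0.05) and neural markers at -0.03 (Mbp -0.48, Sox10 -0.46).

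Uninfected cells showed what 4-OHT does without the fusion. The p53 targets had a median of -0.06 there, with 15 of 41 positive. Mdm2 differed by -0.27 (SE 0.41), Pmaip1 by -0.55 (SE 0.52), Cdkn1a by -0.38 (SE 0.49), Phlda3 by -0.18 (SE 0.24) and Ccng1 by -0.10 (SE 0.56). A second, dimmer Cdkn1a probe set differed by +0.45 (SE 0.74). The p53 target list did not pass camera (adjusted p = 0.913), nor did any of the other 20 lists. With limma, 0 genes passed and 84 had an unadjusted p under 0.05, against 545.8 by chance. Without uninfected vehicle replicate 3, 1 gene passed. With the block 0 genes passed, and 113 had an unadjusted p under 0.05. The fit without the block left differences between replicate numbers in the spread, so 0 genes does not show that 4-OHT had no effect.

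The difference between the 4-OHT effects tests the part of the response that differs between p53ER and uninfected cells. The labels name no cells infected without the fusion, so the fusion cannot be told apart from infection or the vector. For the p53 targets the median difference, p53ER minus uninfected, was +0.46 with 35 of 41 positive, and for the cell death targets +0.46 with 15 of 16 positive. Both lists passed camera with the preset correlation (adjusted p = 1.5e-14 and 1.3e-07) and with an estimated correlation (adjusted p = 0.0276 for each), but not fry (adjusted p = 0.0974 for each). Without the 3 arrays that lay apart, the adjusted p with an estimated correlation was 0.0846 for each. Adjusted over the list alone, 4 genes passed, all higher: Pmaip1 (+3.93, SE 0.74), Mdm2 (+3.19, SE 0.59), Cdkn1a (+2.57, SE 0.70) and Phlda3 (+1.61, SE 0.34). The second Cdkn1a probe set differed by +1.77 (SE 1.05). Over all genes limma called 0, with 168 at an unadjusted p under 0.05 and a smallest adjusted p of 0.338. The second Mdm2 probe set differed by +2.92 (SE 0.40, limma adjusted p = 0.0180 over all probe sets). With the block 1 gene passed, Mdm2 (limma adjusted p = 0.00735), and 7 p53 targets passed when adjusted over the list alone. Without p53ER vehicle replicate 1, and without p53ER vehicle replicate 3, 1 gene passed. The replication genes differed by a median of -0.20 and passed with the preset correlation (adjusted p = 0.00682), a call lost otherwise (adjusted p = 0.931 with an estimated correlation), and lost with the preset correlation too without the 3 arrays (adjusted p = 0.208).

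**Figure D2:**
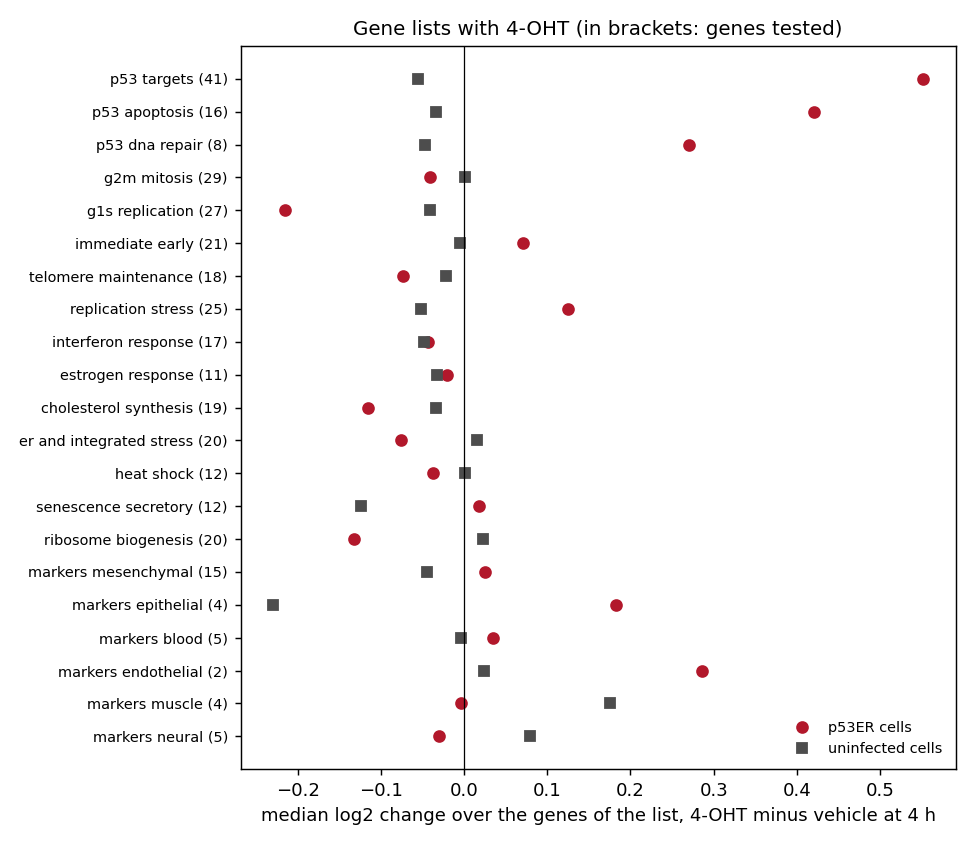
Median log2 change with 4-OHT against vehicle at 4 h over the tested genes of each of the 21 lists, in p53ER cells (circles) and uninfected cells (squares). The p53 targets stand at +0.55 in p53ER and -0.06 in uninfected cells.

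The same 4-OHT arrays set against p53ER cells at 0 h gave a second reference for the response. Mdm2 was 7.52-fold higher (log2 change +2.91, SE 0.41, limma adjusted p = 0.0357) and Pmaip1, near background at 0 h, was higher by a log2 change of +3.29 (SE 0.52, limma adjusted p = 0.0496), again the genes past the threshold, with 453 at an unadjusted p under 0.05. The p53 targets had a median of +0.52, with 33 of 41 positive and 8 past the threshold when adjusted over the list alone, among them Perp (+1.49) and Rap2b (+0.76) beside Cdkn1a (+2.63). The list passed camera with an estimated correlation (adjusted p = 0.0221), as did the cell death targets (adjusted p = 0.0411), but without the 3 arrays that lay apart neither did (adjusted p = 0.0507 and 0.0559 with an estimated correlation). Replication genes had a median of -0.25, with 3 of 27 positive, immediate early genes +0.22, interferon response genes -0.42 and secreted senescence factors +0.36. These 4 lists passed with the preset correlation (adjusted p = 6.8e-07, 0.00293, 0.00182 and 0.0394), all lost otherwise (adjusted p = 0.397, 0.397, 0.696 and 0.696 with an estimated correlation). With the 3 arrays left out the immediate early call was lost with the preset correlation as well (adjusted p = 0.102), the senescence median was +0.58 and mitotic genes moved from -0.03 to -0.36. The 0 h group then held no replicate 3, so these values cannot be told apart from the difference of replicate 3 in p53ER cells. With the block 19 genes passed, 18 higher and 1 lower. The higher ones included, chosen after their values were seen, Cdkn1a, Phlda3, Vegfa (+1.37), Lif (+2.63), Il11 (+2.25) and Cx3cl1 (+1.09), and the lower one was Trim25 (-0.89). Against vehicle Vegfa, Lif, Il11 and Cx3cl1 differed by +0.45, +0.64, +0.29 and +0.28 and did not pass with the block, so their values against 0 h do not single out 4-OHT. Without 4-OHT replicate 1, 2 or 3, or 0 h replicate 1 or 2, 0 genes passed with limma, with 533, 419, 335, 458 and 447 at an unadjusted p under 0.05; without 0 h replicate 3, 2 genes passed, but Mdm2 and Pmaip1 did not (adjusted p = 0.0532 and 0.134). Without the 3 arrays that lay apart, 6 genes passed.

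Vehicle against 0 h shows what 4 h of culture did without 4-OHT. In p53ER cells 0 genes passed with limma, with 333 at an unadjusted p under 0.05, and in uninfected cells 0, with 622. The leukemia inhibitory factor gene Lif differed by +1.99 and +2.06 (SE 1.01 each) in p53ER and uninfected cells, and Cyp51, of cholesterol synthesis, by +0.57 in p53ER cells (SE 0.15), the one gene of its list to pass when adjusted over the list alone (adjusted p = 0.0309), as it was in uninfected cells (adjusted p = 0.0411). The interferon response (median -0.45), secreted senescence factors (+0.38) and ribosome biogenesis (+0.14) passed camera with the preset correlation in p53ER cells (adjusted p = 0.00703, 0.00703 and 0.0384). All 3 were lost otherwise (adjusted p = 0.583 each with an estimated correlation). Leaving out the 3 arrays that lay apart gave medians of +1.002 for senescence factors, +0.29 for ribosome biogenesis and -0.61 for mitotic genes (from -0.05). The last had 1 of 29 positive and passed with the preset correlation (adjusted p = 1.4e-06) and not otherwise (adjusted p = 0.731 with an estimated correlation). The p53ER vehicle group then held replicates 2 and 3, and the 0 h group replicates 1 and 2. In p53ER cells replicate 3 was itself lower in mitotic genes (median -1.08) and higher in senescence factors (+0.79). These medians therefore cannot be told apart from the difference of replicate 3. In uninfected cells mitotic genes (+0.23) and ribosome biogenesis (+0.11) passed with the preset correlation (adjusted p = 0.0281 and 0.0349), and neither otherwise (adjusted p = 0.929 each with an estimated correlation); without the 3 arrays ribosome biogenesis missed with the preset correlation too (adjusted p = 0.0662), and the interferon response moved from -0.27 to -0.53. No gene passed for the difference of the vehicle change between cell types (limma, 0 genes, 235 at an unadjusted p under 0.05). In that difference mitotic genes (median -0.12) and replication stress genes (-0.27) passed with the preset correlation (adjusted p = 0.0301 each), and neither otherwise (adjusted p = 0.974 and 0.923 with an estimated correlation). These medians without the 3 arrays were -0.78 and -0.15, and the replication stress call was lost with the preset correlation (adjusted p = 0.349). Replicate numbers were unbalanced between the groups here too. Without p53ER vehicle replicate 1, and without p53ER vehicle replicate 2, 1 gene passed in p53ER cells.

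Untreated p53ER and uninfected cells were compared to see how the fusion's carriers differed before 4-OHT. On its brightest probe set Esr1, the estrogen receptor gene, differed by +3.80 at 0 h (SE 0.82, limma adjusted p = 0.843) and by +4.34 with vehicle (SE 0.82, adjusted p = 0.454). The uninfected signal was near background, so these sizes depend on the offset (+3.21 and +3.57 with a larger offset, +4.08 and +4.85 with none). Over all alternatives they ran from +2.94 to +4.20 at 0 h and from +2.78 to +5.07 with vehicle. Its other 2 probe sets differed over all 9 p53ER against 9 uninfected arrays by +0.49 and +0.73. The brightest of 3 probe sets assigned to the transcription factor gene Mycn differed by +6.72 at 0 h (SE 0.98, limma adjusted p = 0.0539) and by +7.38 with vehicle (SE 0.98, adjusted p = 0.0174). Some uninfected arrays were near background on it, so these sizes depend on the offset too (+6.33 and +6.84 with a larger offset, +6.90 and +7.66 with none). The alternatives gave +5.19 to +7.23 at 0 h and +6.59 to +7.93 with vehicle. With vehicle Mycn was the 1 gene past the threshold, and at 0 h limma called 0 genes, with 262 and 312 at an unadjusted p under 0.05. The block ended the call with vehicle (adjusted p = 0.239). So did leaving out uninfected vehicle replicate 1, 2 or 3 (adjusted p = 0.0647, 0.187 and 0.0788), p53ER vehicle replicate 3 (0.159) or the 3 arrays that lay apart (0.121), while 2 genes passed without p53ER vehicle replicate 1 and 2 without replicate 2. At 0 h 1 gene, not Mycn (adjusted p = 0.0868), passed without uninfected 0 h replicate 2.

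**Figure D3:**
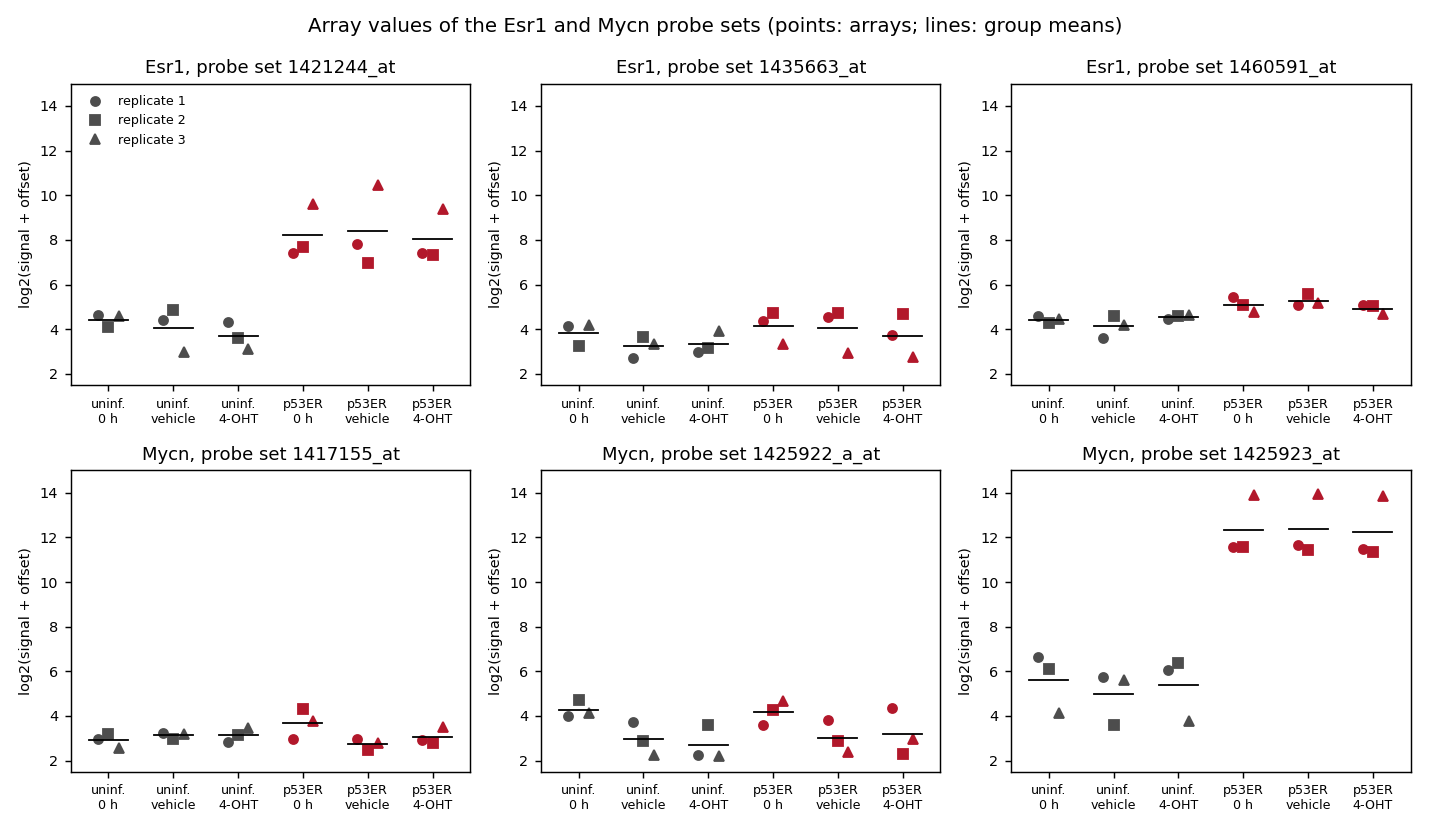
Log2 signal of the 3 Esr1 and 3 Mycn probe sets on each array, by group; points are arrays, their shapes the replicate numbers, and lines the group means of 3 arrays. The brightest Mycn probe set averaged 12.3 over p53ER and 5.34 over uninfected arrays.

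The p53 targets differed by a median of +0.26 at 0 h (29 of 41 positive) and +0.10 with vehicle (28 of 41), where Trp53inp1 stood at +1.38 and +0.69. The list passed camera with the preset correlation in both comparisons (adjusted p = 0.00380 and 0.0399), and in neither otherwise (adjusted p = 0.456 and 0.635 with an estimated correlation). Replication genes were lower in median, by -0.28 at 0 h and -0.21 with vehicle (adjusted p = 1.9e-06 and 8.0e-07 with the preset correlation). These were lost too (adjusted p = 0.456 and 0.354 with an estimated correlation). Mitotic genes stood at -0.19 at 0 h and -0.46 with vehicle, where 0 of 29 were positive (adjusted p = 0.0469 and 4.8e-10 with the preset correlation), and both were lost (adjusted p = 0.783 and 0.354 with an estimated correlation). At 0 h the interferon response (+0.36) and muscle markers (-0.51) also passed with the preset correlation only (adjusted p = 0.77 and 0.456 with an estimated correlation). With vehicle the same held for replication stress (-0.25), cholesterol synthesis (+0.18), endoplasmic reticulum and integrated stress (+0.16) and ribosome biogenesis (-0.13), with adjusted p = 0.241, 0.241, 0.241 and 0.635 with an estimated correlation. Several of these medians changed when the 3 arrays that lay apart were left out. Without them, at 0 h, the mitotic genes changed sign to +0.16 (24 of 29 positive), the p53 targets stood at +0.15 (26 of 41), the interferon response at +0.06 and muscle markers at -0.22, and none of these 4 passed with the preset correlation (adjusted p = 0.111, 0.140, 0.852 and 0.256). With vehicle the p53 targets stood at +0.26 and replication stress at -0.10, and the calls of endoplasmic reticulum stress and ribosome biogenesis were lost (adjusted p = 0.0695 and 0.174 with the preset correlation). Leaving out the 3 arrays removed p53ER replicate 3 and uninfected replicate 2 at 0 h, and p53ER replicate 1 with vehicle. At 0 h p53ER replicate 3 was itself lower in mitotic genes (median -1.01). These changes therefore cannot be told apart from differences between replicate numbers.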

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

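All tests of explanations and of other splits of the arrays in this part were chosen after the results were seen; the difference of the 4-OHT effect between the cell types was planned.

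A planned test of the difference singled out the response to 4-OHT in p53ER against uninfected cells. The difference was 3.18876 (log2) for Mdm2, which passed with the replicate number as a block (limma adjusted p = 0.00735) and not without it (0.338; 0.00546 to 1.00 over the alternatives); the second Mdm2 probe set differed by +2.92 (SE 0.40, limma adjusted p = 0.0180 over all probe sets). The median difference was 0.459492 for the p53 targets and 0.457951 for the cell death targets, and both lists passed camera with an estimated correlation (adjusted p = 0.0276 each) but not fry (0.0974 each), and without the 3 arrays that lay apart the adjusted p was 0.0846 each with an estimated correlation. Of 100 drawn splits of the arrays, 13 gave a median as far from 0 for the p53 targets (highest other 0.632) and 5 for the cell death targets (0.562), the real one included. Among the 17 that part all pairs, 3 and 2 did. With the block the real split gave 1 gene, and 5 of 100 splits gave as many, the real one included (highest other 1), 2 of them among those 17. Chance was not excluded for any of these 3 results. Splits of p53ER and uninfected arrays were drawn independently, so a draw could keep the real p53ER grouping and regroup uninfected arrays only. Such a draw keeps the p53ER response, which made a share under 0.05 hard to reach, so these shares do not decide the question. The 17 splits are too few for a share under 0.05. In each other split that gave 1 gene with the block, that gene was a p53 target, so the count does not test Mdm2 itself.

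Other splits of the same arrays were counted for each comparison. The 6 arrays of a comparison give 10 splits, too few for a share under 0.05. In p53ER cells with 4-OHT the real split gave 2 genes against vehicle, with 2 p53 targets raised, and 2 against 0 h, each in 1 of 10 splits, and the highest other gave 0. Replicate numbers paired the arrays there, and among the 4 splits that part all pairs the highest other also gave 0. The real split gave 0 genes in uninfected cells with 4-OHT (highest other 0), in p53ER cells with vehicle against 0 h (0) and in uninfected cells with vehicle against 0 h (1), so that 10 of 10 splits gave as many, which a real count of 0 makes certain. Between the untreated cell types the real split gave 1 gene with vehicle (1 of 10 splits, highest other 0) and 0 at 0 h (10 of 10, highest other 55). That highest split put uninfected replicates 2 and 3 together with p53ER replicate 3, which points to a structure of the samples. Uninfected 0 h replicate 2 and p53ER 0 h replicate 3 are among the 3 arrays that lay apart. Uninfected 0 h replicate 3 is among the 6 with a low median correlation. For the differences of the 4-OHT effect and of the vehicle effect the real count was 0 too, so 100 of 100 drawn splits gave as many and this count says nothing about chance. The highest other was 1 for the first and 679 for the second, which again points to a structure of the samples.

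The brightest of 3 Mycn probe sets averaged 12.3 ± 1.19 over 9 p53ER arrays and 5.34 ± 1.19 over 9 uninfected arrays (SD), some of them near background, with no overlap (lowest p53ER 11.3, highest uninfected 6.66). The other 2 Mycn probe sets differed by 0.13267 on average (SE 0.26), but both were near background in both cell types, so a transcript read by all 3 stays open. The probe set may also read sequence of the vector that carries the fusion. In p53ER arrays it was higher in replicate 3 than in replicates 1 and 2 by 2.36867 (SE 0.05), close to the brightest Esr1 probe set (+2.38, SE 0.35). The SEs of these differences measure the spread between arrays and not between replicates. The other 2 Esr1 probe sets went the other way, by -1.45 (SE 0.23) on 1 near background (mean 3.97 in p53ER arrays) and by -0.34 (SE 0.18) on 1 that was dim (5.10), so this reading rests on 1 Esr1 probe set. A transcript that this probe set alone reads stays open, as no sequence was tested.

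Uninfected 0 h replicate 2, p53ER vehicle replicate 1 and p53ER 0 h replicate 3 lay apart on the first principal component (scores 56.6, 53.3 and 27.2), and were singled out after that was seen. Against the other replicates of the group, Malat1 differed by -3.16, -4.62 and -0.38 in these arrays, in that order. Smc2 differed by -2.96, -3.28 and -2.08, and Taok1 by -5.34, -6.18 and -0.60. These genes were picked after their values were seen. RNA degradation that raises 3' over 5' signal was argued against for the control transcripts only. The actin log2 ratio differed from the other 15 arrays by -0.0508324 (SE 0.02) and the Gapdh ratio by +0.01 (SE 0.09). Loss of other RNAs was not tested, so RNA quality in general stays open. Brightness was argued against, as the trimmed mean was 122.785 in the brightest of the 3 and 58.0 in the dimmest, on both sides of the median of the others (81.9). The arrays are of 3 different groups and no biological explanation was tested, so the cause stays open.

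Replicate 3 differed from replicates 1 and 2 in 1329 genes in p53ER cells and 1140 in uninfected cells, and by a different amount in 34 (limma, adjusted p under 0.05). Arrays that share number 3 counted as separate in these tests, so the p-values measure the spread between arrays and not between replicates. In p53ER cells mitotic genes had a median of -1.08, with 20 of 29 lower, against -0.09 in uninfected cells, a difference of -0.94 (camera adjusted p = 0.00428 with an estimated correlation). A cause common to both cell types was argued against for the mitotic genes, since their lowest median in an uninfected group was -0.210032, against -1.01 to -1.09 in the p53ER groups. More fusion in replicate 3 of p53ER cells is a candidate explanation. The brightest Esr1 probe set was higher there by 2.38, though the other 2 were lower there, by -1.45 (near background) and -0.34. The p53 targets differed by 0.350931 more than in uninfected cells, weakly (camera p = 0.0176, adjusted p = 0.0647 with an estimated correlation). Their median in replicate 3 against the others was +0.67 with 4-OHT, +0.22 at 0 h and +0.28 with vehicle, and +0.08 to +0.14 in the uninfected groups. The mitotic genes were as low without 4-OHT (-1.01 at 0 h and -1.09 with vehicle) as with it (-1.07). Whether either pattern differed by treatment was not tested. Each group has 1 array with number 3, so passage, culture and clone stay open.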

How the results depend on the processing

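The alternatives that left out the 3 arrays lying apart, or replicate 3 of every group, were chosen after the data were seen; the others were planned. The cause of the changes below was not tested, except that leaving out arrays or using only the groups compared lowers the number of arrays. Leaving out the 3 arrays also left groups with different replicate numbers.

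With the replicate number as a block, 8 genes passed in p53ER cells with 4-OHT against vehicle in place of 2, 4 of them p53 targets, and 19 against 0 h in place of 2; the difference of the 4-OHT effect gave 1 in place of 0, and p53ER against uninfected cells with vehicle 0 in place of 1. Numbers paired the arrays in the first 3 of these comparisons and not in the last. For Mdm2 the SE fell from 0.41 to 0.27 with the block.

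For p53ER cells with 4-OHT against vehicle the count was 1 with no offset, 4 with a larger offset, 1 with a stricter filter, 0 with only the groups compared, 4 with array weights and 9 without the 3 arrays and with the block. Without the 3 arrays alone it was 3, sharing 1 gene with the 2 reported, and Mdm2 did not pass (adjusted p = 0.130; 0.000272 to 0.998 over the alternatives). The p53 targets raised were 1 with no offset, 1 with a stricter filter, 0 with only the groups compared and 5 without the 3 arrays and with the block. Against 0 h the count was 1 with no offset, 1 with a stricter filter, 0 with only the groups compared, 28 with array weights, 6 without the 3 arrays and 26 without them and with the block. Array weights gave 2 genes in uninfected cells with 4-OHT, 2 in the difference of the 4-OHT effect and 1 in p53ER cells with vehicle against 0 h. That difference also gave 1 with all probe sets and 2 without the 3 arrays and with the block, and p53ER cells with vehicle against 0 h gave 1 without the 3 arrays.

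Between the untreated cell types at 0 h, quantile normalization, a larger offset, a stricter filter, leaving out the 3 arrays, doing so with the block and leaving out replicate 3 each gave 1 gene. It was Mycn in the first 3, Psrc1 in the next 2, a gene named after its values were seen, and Esr1 in the last. With vehicle, no filter gave 0, only the groups compared 0, leaving out the 3 arrays 0, and doing so with the block 3.

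Leaving out 1 array at a time gave 0 to 5 genes in p53ER cells with 4-OHT against vehicle (p53 targets raised 0 to 5) and 0 to 2 against 0 h. It gave 0 to 1 in uninfected cells with 4-OHT, in the difference of the 4-OHT effect, in p53ER cells with vehicle against 0 h and between the cell types at 0 h, and 0 to 2 between them with vehicle. A group left with 2 arrays took its spread from all groups. Uninfected cells with vehicle against 0 h and the difference of the vehicle effect gave 0 genes under every alternative (limma; 622 and 235 at an unadjusted p under 0.05 in the fit reported).

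Of 21 gene values followed over 19 to 26 alternatives each, 417 values in all, 0 reversed. Most of these values were large in the fit reported and the alternatives reuse most of the same arrays, so a reversal was unlikely from the start. The log2 change in p53ER cells with 4-OHT against vehicle ran from 2.50 to 3.49 for Mdm2, which missed the threshold under 7 of 20 alternatives, from 2.78 to 3.73 for Pmaip1 (8 of 19) and from 1.45 to 2.50 for Zfp365, which passed under 1 of 19. Signal near background limits the third Mdm2 probe set, with a mean of 4.53 with 4-OHT.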

Other observations

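The tests behind these values were chosen after the differences between replicates were seen.

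Some genes that differed between replicate 3 and replicates 1 and 2 were picked after their values were seen. The p-values for replicate 3 here, too, measure the spread between arrays and not between replicates. Gsta4, a glutathione transferase gene, differed by +3.51 in p53ER and +2.62 in uninfected cells, and Aldh1a1 by -4.04 and -5.02. Nqo1 (+1.65 and +0.60), Aldh3a1 (+2.86 and +0.80) and Txnrd1 (+1.26 and +0.32) were higher by more in p53ER cells, and in uninfected cells Aldh3a1 and Txnrd1 did not pass (limma adjusted p = 0.0536 and 0.0758) (limma adjusted p of the difference = 0.01001, 0.0169 and 0.0109). Gpnmb differed by -1.001 and -3.93 (adjusted p of the difference = 0.000710). The cyclin gene Ccna2 differed by -1.23 in p53ER and +0.06 in uninfected cells (0.01001), and Ube2c by -1.53 and -0.34 (0.0185). Secreted senescence factors were higher by a median of +0.79 in p53ER cells, with 12 of 12 positive (camera adjusted p = 0.0386 with an estimated correlation), and by +0.49 in uninfected cells, where the list passed with the preset correlation (adjusted p = 0.00104) and not otherwise (adjusted p = 0.122 with an estimated correlation). The difference between the cell types for that list did not pass (camera adjusted p = 0.309 with an estimated correlation).

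Over the untreated groups together, 0 h and vehicle, 2 genes passed between p53ER and uninfected cells: Mycn (+7.05, limma adjusted p = 0.000363) and Esr1 (+4.07, adjusted p = 0.0201). With the replicate number as a block Mycn passed (adjusted p = 0.0123) and Esr1 did not (0.121). Both read the same arrays as the separate comparisons, so they add no independent test.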
